A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

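Expression was measured on one-colour Affymetrix arrays of S. cerevisiae, 3 with wild-type histone H2A and 3 with H2A R78A. The values are probe set signal intensities as deposited; the authors' notes name MAS5 and limma, whose versions are not given in the sources used here. The deposited intensities are on a linear scale and have a trimmed mean (2% at each end) of 500 on every array. No further normalization was applied for the values reported, and log2 was taken. Scanner files and detection calls were not used here. The number of arrays limits the precision.

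Of 5900 probe sets, 5498 were paired with 1 yeast gene each, after 12 symbols had been updated to those of the annotation table. The 137 Affymetrix controls, 47 vector or reporter probe sets and 218 probe sets without a gene name were left out of the gene tests. For the 47 genes with several probe sets, the one with the highest mean was used, which left 5449 genes. Of these, 97 were read by probe sets ending in _s_at and 20 by probe sets ending in _x_at, which can match several genes. The background level was set at the 25th percentile of the mean log2 signals of the tested genes, 7.86, a signal of 232.

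Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, two-sided), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Differences are log2 H2A R78A minus wild type, and signals are means ± SD. For 38 gene lists with at least 4 measured members, limma's camera was run with a preset correlation of 0.01 and adjusted over the lists. For each list the members past the threshold were counted, adjusted over all genes and over the list alone. The matched-signal value of a list is the median over its members of the median difference of non-members nearest in mean signal. Lists overlap, so SPI1 and PGM2, for example, count in more than one. Telomere-proximal genes were the first 8 from each chromosome end in the order of the gene table, tested with camera and Fisher's exact test. Chromosomes were tested with camera, adjusted over 16. The comparison, tests, lists, thresholds and the alternatives described as set beforehand were chosen before the data were examined.

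Named genes followed a rule. Named were HTA1, HTA2, HTB1 and HTB2, then the 10 largest increases and 10 largest decreases among genes past the threshold whose groups did not overlap and whose brighter group exceeded the background level, and for each list up to 4 members past the threshold with the largest absolute difference, or up to 2 where none passed. Other genes named in the text were chosen after their values were seen.

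The groups share replicate numbers. After removing group means, residuals of arrays with the same number correlated with r = 0.206, 0.383 and 0.427 across genes, and those with different numbers with r from -0.449 to 0.154, and each array correlated best with its own number over all genes. Among genes above the background level, mutant replicate 1 correlated better with wild-type replicate 3 (r = 0.194) than with wild-type replicate 1 (r = 0.106). The replicate number was therefore also fitted as a block. Alternatives set beforehand were quantile normalization, median centring, a background filter, raising of low values, the mean of all probe sets, limma without trend, robust limma, array weights, the block, leaving out each array, other thresholds, fry, camera on ranks and camera with an estimated correlation. Cyclic loess and quantile normalization with the block were added after the data had been seen.

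The limma procedure was tested on simulated arrays, 3 against 3, with 5449 genes. It recovered 32% of made differences of 0.25, 92% of 0.5 and 100% of 1 on the log2 scale. Of 167 calls 9 were false (5.4%), and 0 of 38 lists without a made shift were called. Noise was drawn independently for each gene, so the list result does not cover lists whose members vary together. Differences were made only in genes above the background level, so the recovery does not describe dim genes. Figures were drawn with matplotlib 3.10.9.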

Results

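Expression was measured in Saccharomyces cerevisiae carrying either wild-type histone H2A or the R78A form, in which an arginine of H2A is replaced by alanine. The arginine is a sprocket arginine, one of the histone side chains that reach into the minor groove where DNA faces the histone core of the nucleosome. The comparison asks which transcripts depend on that contact. Each group had 3 arrays, and cells were harvested in mid-log growth in rich glucose medium at 30 °C. RNA was turned into biotin-labelled cRNA and hybridised to one-colour Affymetrix arrays, and 5449 genes were tested.

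The deposited signals had the same trimmed mean of 500 on every array, so levels are relative to the other transcripts of the same array. The median signal was 404 on each wild-type array and 414 to 432 on the mutant arrays. The mutant arrays had a narrower spread. The 10th percentile of the genes lay at 90.2 to 102 in wild type and at 121 to 135 in the mutant, and the 90th percentile at 1070 to 1106 and at 997.1 to 1050. Across the genes above the background level, log2 signals of arrays of the same group correlated with r between 0.974 and 0.988, and those of different groups with r between 0.933 and 0.954. Genes are not independent replicates in these correlations. The number of arrays limits the precision of every difference. The labels do not say that the replicates were separate cultures, so the p-values measure the spread between these samples, which may be technical.

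The comparison of the transcripts of the mutated protein depended on the scaling, the weights and the arrays used. HTA1, a gene for H2A, had a signal of 1794 ± 63.2 in wild type and 1839 ± 104 in the mutant (mean ± SD, n = 3), a log2 difference of 0.03 with a limma adjusted p of 0.686. After quantile normalization HTA1 was higher, with a difference of 0.19 and an adjusted p of 0.00932, and with cyclic loess it was higher by 0.20 (adjusted p = 0.011). The probe set standing for HTA2, the other H2A gene, carries a suffix that marks sequence shared between genes, and gave 1470 ± 45.7 and 1332 ± 80.9 (log2 difference -0.14, limma adjusted p = 0.0954). That shared probe set passed as lower with array weights (-0.18, limma adjusted p = 0.0168) and without mutant replicate 2 (-0.19, 0.0354). Its signal cannot be credited to HTA2, whose specific probe set read at most 3.30. HTB1, for histone H2B, gave 1679 ± 90.2 and 1603 ± 80.4 (limma adjusted p = 0.444). The specific probe sets of HTA2, HTB2 and HHT1 stayed at or near the level of the Affymetrix tag controls on all arrays, with values of at most 3.30, 0.688 and 5.49 against at most 1.94, so no fold is given for them. The probe set standing for HHF1, for histone H4, also carries the suffix for shared sequence, so its signal cannot be credited to HHF1 alone. The signal was 1.16-fold lower in the mutant (log2 -0.21, limma adjusted p = 0.037). That limma call ended after quantile normalization (-0.06, adjusted p = 0.374), with low values raised (adjusted p = 0.106) and without a variance trend (0.0904). It also ended when any array other than mutant replicate 2 was left out (0.0514 to 0.106). The probe sets cannot read a point mutation, so the genotype was not checked.

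The mutant differed from wild type across a broad set of genes, and the larger differences were increases. PRM2 (YIL037C), a pheromone-regulated gene needed for nuclear fusion in mating, rose 4.07-fold, from a signal of 79.5 ± 7.15 to 322.8 ± 15.0. TSA2 (YDR453C), a stress-inducible peroxiredoxin, rose 3.65-fold from 74.8 ± 3.29 to 273.3 ± 16.1. SPI1 (YER150W), a cell wall protein, rose 3.35-fold from 200.7 ± 29.3 to 672 ± 99.7, and HUG1 (YML058W-A), an inhibitor of ribonucleotide reductase, rose 3.12-fold from 216 ± 51.3 to 662 ± 60.7. The rest of the 10 largest increases among genes above the background level in the brighter group were HMS1, GND2 of the pentose phosphate pathway, the pyruvate decarboxylase gene PDC6, DDI3, the glucose-repressed alcohol dehydrogenase gene ADH2 and RTC3, which were 3.22, 3.21, 3.10, 3.07, 2.97 and 2.83-fold higher. Standard errors of these 10 log2 differences lay between 0.08 and 0.16, and the 10 limma adjusted p-values were at most 4.23e-05. DDI3 has a nearly identical copy in the genome, which the array may not separate from it.

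Among genes above the background level in the brighter group, the largest decrease on the deposited scale was that of FIT2 (YOR382W), a cell wall mannoprotein that helps retain siderophore iron, which was 2.04-fold lower (644.5 ± 64.1 to 314.5 ± 3.98, limma adjusted p = 1.74e-05). The acid phosphatase gene PHO11 (YAR071W) was 1.87-fold lower (1341 ± 46.7 to 716.8 ± 31.9, limma adjusted p = 5.98e-06). MNS1, a mannosidase of the endoplasmic reticulum, fell by 0.83 on the log2 scale, and AAD3, a putative aryl-alcohol dehydrogenase, fell by 0.81. YDL241W, the methyltransferase gene MHT1, YLR126C, YDR541C, the siderophore transporter gene ENB1 and the glutaredoxin gene GRX4 had log2 differences of -0.78, -0.77, -0.76, -0.72, -0.70 and -0.61. After quantile normalization the decrease of PHO11 was smaller (-0.83), and the other decreases were larger, AAD3 reaching -1.03 and MHT1 -0.98. All 20 of these largest increases and decreases kept their direction and an adjusted p below 0.05 under every alternative that was chosen before the data were examined and that tested them.

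**Figure D1:**
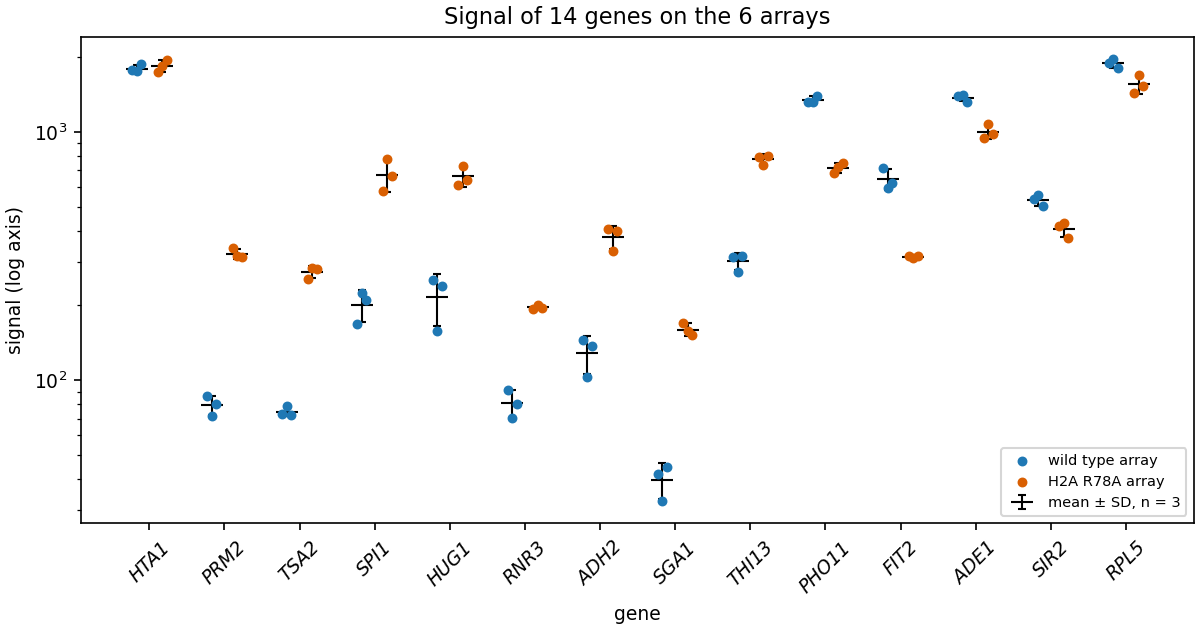
Signal of 14 named genes (log axis) on the 3 wild-type arrays (blue) and the 3 H2A R78A arrays (orange); black bars give the mean ± SD of n = 3. The arrays of the groups overlap for HTA1, and PRM2 lies near 79.5 on the wild-type arrays and near 322.8 on the mutant arrays.

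In all, 976 genes were higher and 500 lower in the mutant at an adjusted p below 0.05 in limma's moderated test, 27.1% of the genes tested. Without mutant replicate 3 the total of 1476 fell to 888, with 194 lower, and without mutant replicate 1 to 911, with 228 lower; without wild-type replicate 1 there were 228 lower and without wild-type replicate 2 there were 308. A difference of at least 2-fold was seen for 141 of the higher genes and for 1 of the lower, FIT2, on the deposited scale, for 47 and 6 after quantile normalization and for 53 and 4 with cyclic loess. At 1.5-fold the counts were 439 and 17 on the deposited scale and 209 and 81 after quantile normalization. The 6 values did not overlap between the groups for 961 of the higher and 481 of the lower genes, and over all genes for 43.1%, where chance gives 10%. The split between directions depended on the scaling. Increases made up 66.1% of the calls on the deposited scale, 60.8% (622 higher, 401 lower) with cyclic loess, 51.0% (566 higher, 544 lower) after quantile normalization and 48.1% (811 higher, 875 lower) when each array was centred on its median. With the replicate number as a block, 1292 genes were higher and 857 lower.

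The direction followed signal strength. The 246 genes with a mean log2 signal below 6 had a median difference of 0.51, with 114 higher and 0 lower. The 593 genes with a mean log2 signal above 10 had a median of -0.14, with 8 higher and 173 lower. After quantile normalization the medians of these groups were -0.06 and -0.01.

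**Figure D2:**
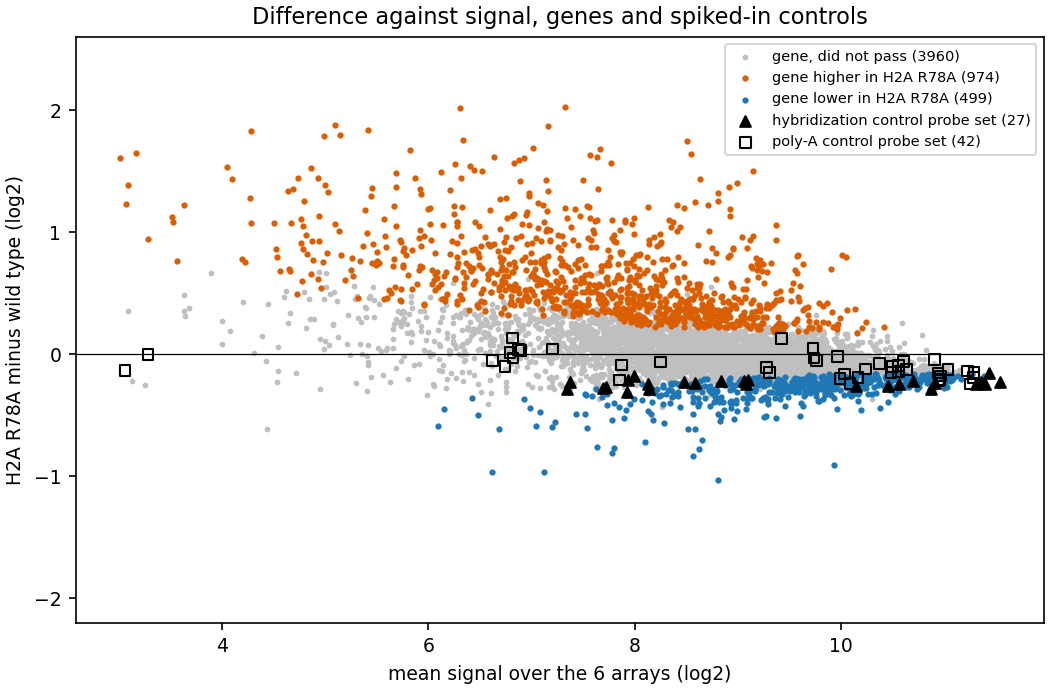
Log2 difference between H2A R78A and wild type against mean log2 signal over the 6 arrays, for the 5433 genes with a mean log2 signal above 3 (orange, higher; blue, lower; grey, did not pass) and for 27 hybridization control (triangles) and 42 poly-A control (squares) probe sets. Genes below a log2 signal of 6 lie mostly above 0, with a median of 0.51, while the hybridization controls have a median of -0.24.

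Genes of the general stress response rose together. Of 64 measured members, 54 were higher and 0 lower (56 higher when adjusted over the list alone), with a median log2 difference of 0.74. GRE1, which encodes a small hydrophilic stress protein, rose from 44.3 ± 7.34 to 149 ± 14.3 (log2 1.75), and NQM1, a transaldolase gene, from 70.1 ± 7.17 to 212.5 ± 10.5 (log2 1.60). GND2 and SPI1 belong to the same list. The list stood above other genes in limma's camera with a preset correlation (adjusted p = 1.04e-26), and had an adjusted p of 0.161 with an estimated correlation. Genes of matched signal outside the list had a median difference of 0.05, and after quantile normalization the list's median was 0.70.

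Meiosis and sporulation genes, which growing haploid cells keep low, were higher in 40 of 61 measured cases and lower in 2 (42 and 2 adjusted over the list alone; median log2 0.56, limma camera adjusted p = 9.20e-12, 0.248 with an estimated correlation). SGA1, a sporulation glucoamylase, went from 39.8 ± 6.44 to 160 ± 9.52 (log2 2.02, limma adjusted p = 1.02e-05), SPS19 from 51.8 ± 5.27 to 147 ± 11.1 (log2 1.51) and the meiotic chromosome axis gene HOP1 from 38.1 ± 5.70 to 97.2 ± 8.84 (log2 1.36). These are dim probe sets, and the HOP1 call ended when values below the 10th percentile were raised to it. Genes of matched signal had a median of 0.25, and quantile normalization brought the list to 23 higher and 3 lower members, a median of 0.26 and an adjusted p of 9.36e-07.

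Genes for thiamine and pyridoxine synthesis were higher in 9 of 17 cases and lower in 1 (12 and 1 adjusted over the list alone; median log2 0.49, camera adjusted p = 6.97e-05, 0.248 with an estimated correlation). After quantile normalization 8 were higher and 1 lower, with a median of 0.34. THI13, one of several nearly identical genes for a thiamine precursor enzyme, rose 2.58-fold from 301 ± 24.1 to 775 ± 37.5, and the thiamine transporter gene THI7 rose 2.14-fold from 221 ± 22.6 to 472 ± 26.5. Anaerobic and cell wall mannoprotein genes were higher in 15 of 22 cases and lower in 0 (17 higher adjusted over the list alone; camera adjusted p = 1.61e-05, 0.248 with an estimated correlation), with a median log2 difference of 0.47 that was 0.23 after quantile normalization. DAN1 rose from 16.5 ± 3.38 to 44.1 ± 2.78 and TIR1 from 221 ± 50.9 to 427.5 ± 18.4; SPI1 is also on this list, and the DAN1 call ended when low values were raised.

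Genes of respiratory and glyoxylate metabolism were shifted upward. The tricarboxylic acid and glyoxylate cycle list had 14 of 27 members higher and 1 lower (17 and 2 adjusted over the list alone; median log2 0.27, camera adjusted p = 0.00171, 0.248 with an estimated correlation), led by the malate synthase gene MLS1 (57.2 ± 4.24 to 175.5 ± 18.6). The respiratory chain and ATP synthase list had 9 of 39 members higher and 0 lower (8 higher adjusted over the list alone; median log2 0.16, camera adjusted p = 0.00168, 0.407 with an estimated correlation), and 14 higher with the replicate block. NDE2, an external NADH dehydrogenase, went from 48.8 ± 5.56 to 132 ± 7.76 and the cytochrome c isoform gene CYC7 from 116 ± 9.24 to 240 ± 32.2; these signals are dim, and the log2 differences of 1.44 and 1.04 were 1.01 and 0.76 after quantile normalization. Quantile normalization gave 11 higher and 1 lower and a median of 0.18 for the tricarboxylic acid list, and 10 higher and a median of 0.15 for the respiratory list. Filtering out genes below the background level ended the call for the tricarboxylic acid list (limma camera adjusted p = 0.0889).

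Among DNA damage response genes, 11 of 32 were higher and 0 lower (12 and 1 adjusted over the list alone; median log2 0.17, camera adjusted p = 0.0117, 0.248 with an estimated correlation). The ribonucleotide reductase gene RNR3, a classic damage-induced gene, rose 2.45-fold from 80.6 ± 10.4 to 197 ± 2.88, beside HUG1, DDI3 and the polyubiquitin gene UBI4, which is also a stress gene and rose 2.12-fold. After quantile normalization 7 members were higher and 1 lower, the median was 0.02, and the list no longer passed (limma camera adjusted p = 0.0696), while these 4 genes did.

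Protein synthesis genes lay slightly lower on the deposited scale. So did the spiked hybridization and poly-A controls, with median log2 differences of -0.24 and -0.11. Of 127 cytosolic ribosomal protein genes 59 were lower and 0 higher (85 lower adjusted over the list alone), with a median log2 difference of -0.17 and a camera adjusted p of 2.81e-19, or 0.248 with an estimated correlation. RPS22B went from 1651 ± 11.3 to 1317 ± 8.81. These are among the brightest probe sets, and non-members of matched signal had a median of -0.14. After quantile normalization 3 members were lower, the median was -0.02 and the list did not pass (limma camera adjusted p = 0.391); with the replicate block 102 were lower. Many ribosomal protein genes have near-identical copies. Ribosome biogenesis genes were lower in 14 of 99 cases and higher in 1 (0 and 0 adjusted over the list alone; median log2 -0.12, camera adjusted p = 2.69e-08, 0.248 with an estimated correlation). Quantile normalization left 6 lower, a median of -0.07 and an adjusted p of 0.024, and the replicate block gave 38 lower. RRP1 was 1.20-fold lower (1008 ± 22.2 to 841 ± 26).

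Among phosphate and purine genes, more members were lower than higher. In the phosphate regulon 8 of 17 members were lower and 2 higher (8 and 2 adjusted over the list alone; median log2 -0.14, camera adjusted p = 6.41e-04, 0.248 with an estimated correlation). Beside PHO11, the sodium-phosphate cotransporter gene PHO89 was 1.95-fold lower (195 ± 18.3 to 100.1 ± 11.2), and after quantile normalization its log2 difference of -1.26 exceeded that of FIT2 (-1.09), as did that of PHM6 (-1.37), a dim gene whose call ended when low values were raised (-0.30, limma adjusted p = 0.167), while PHM8, a phosphatase gene, was 1.67-fold higher. PHO11 has a near-identical copy, PHO12. Quantile normalization left 5 lower and 1 higher, with a median of -0.07 and an adjusted p of 0.0171. Of 20 genes of purine synthesis and one-carbon metabolism 11 were lower and 2 higher (13 and 2 adjusted over the list alone; median log2 -0.18, camera adjusted p = 1.48e-04, 0.248 with an estimated correlation). ADE1 was 1.37-fold lower (1371 ± 45.9 to 1001 ± 69.9). After quantile normalization 5 were lower and 1 higher, and the list did not pass (limma camera adjusted p = 0.060).

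Cell cycle genes of G1/S and G2/M were shifted downward. Of 39 G1/S genes 5 were lower and 1 higher (3 and 1 adjusted over the list alone; median log2 -0.07, camera adjusted p = 0.0125, 0.248 with an estimated correlation), and of 20 G2/M genes 6 were lower and 0 higher (7 lower adjusted over the list alone; median log2 -0.11, camera adjusted p = 0.00226, 0.248 with an estimated correlation). After quantile normalization the G1/S list had 6 lower and 1 higher (median -0.11) and the G2/M list 5 lower (median -0.15). CLB6, an S-phase cyclin gene, went from 219 ± 34.6 to 155 ± 5.55 (limma adjusted p = 0.0135), and the kinase gene KIN3 from 375 ± 49.3 to 282 ± 5.95 (adjusted p = 0.0124). The G1/S call ended when genes below the background level were filtered out (adjusted p = 0.247), and the CLB6 call when wild-type replicate 1 was left out (limma adjusted p = 0.0538). With low values raised, the calls for CLB6 (0.0593) and KIN3 (0.062) ended in limma.

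**Figure D3:**
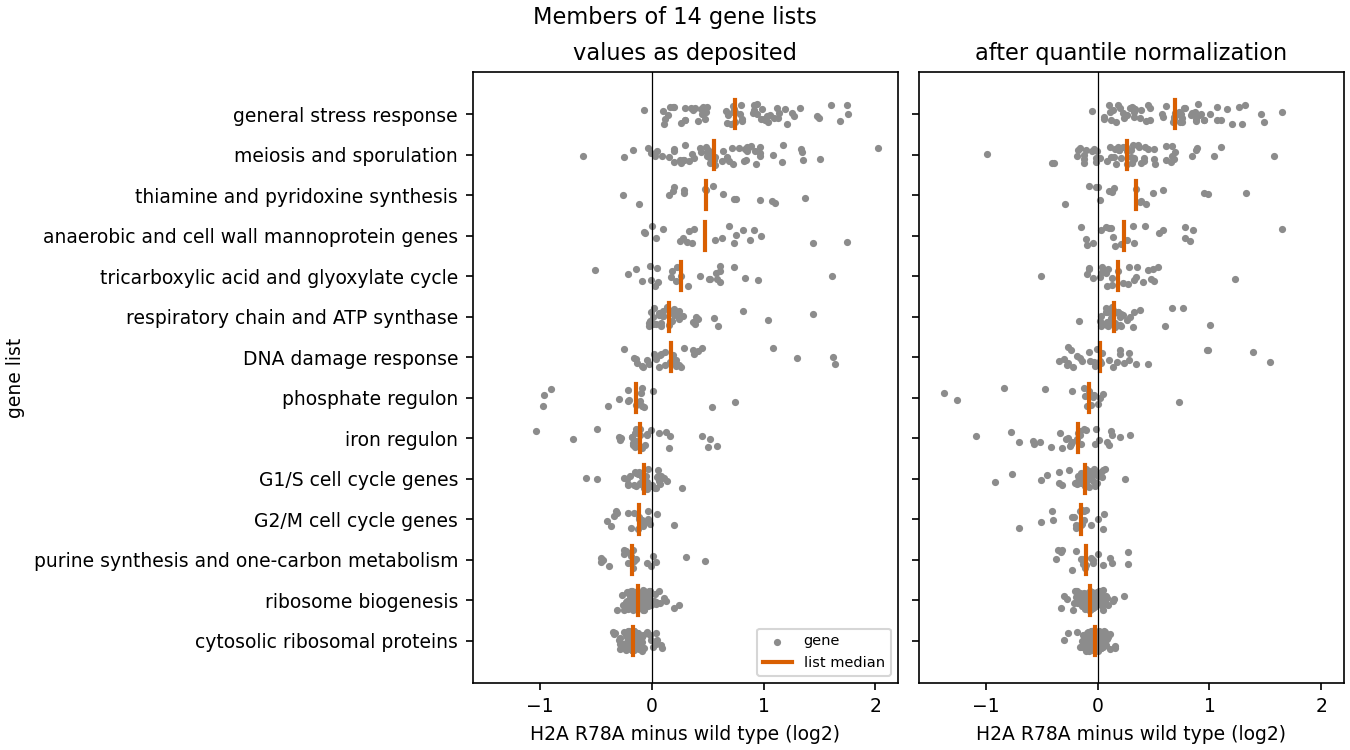
Log2 difference between H2A R78A and wild type for each measured member (grey points) of 14 gene lists, from the deposited values (left) and after quantile normalization (right); orange lines are list medians. The general stress list keeps a median of 0.74 on the left and 0.70 on the right, and the ribosomal protein list moves from -0.17 to -0.02.

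Silencing near chromosome ends depends on intact nucleosomes, so the first 8 genes from each chromosome end were compared with all others. Of 172 measured genes 49 (28.5%) were higher, against 17.6% of the other 5277 genes (Fisher's exact test, two-sided, p = 5.32e-04), and 21 (12.2%) were lower, against 9.08% (p = 0.178). Their median log2 difference was 0.13, against 0.02 for the others, and camera gave p = 0.0314, or p = 0.430 with an estimated correlation. Their median log2 signal was 7.51, against 8.73 for the others. After quantile normalization 31 (18.0%) were higher and 35 (20.3%) lower, with Fisher's exact p of 0.00204 and 4.13e-05, and camera showed no shift to either side (p = 0.962). The excess of the median over other genes was 0.107, and the camera call also ended without wild-type replicate 2 (excess 0.081), without mutant replicate 1 (0.079), with the background filter (0.019), with low values raised (0), with the first 4 genes (0.122) and with the first 16 genes (0.048). With the first 4 genes the share of higher genes did not pass either (22.1% against 17.9%, Fisher's exact p = 0.343). The share of lower genes passed in 4 of the 6 runs with an array left out (Fisher's exact p from 0.0175 to 0.0268). Among silencing factors, SIR2 itself was 1.31-fold lower (531 ± 28.0 to 406 ± 27.5, limma adjusted p = 0.00429).

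No chromosome moved as a whole. The median log2 difference ranged from 0.003 on chromosome XIII to 0.046 on chromosome III, all camera adjusted p-values were 0.981, and 0 of the 16 nuclear chromosomes passed in limma's camera under any alternative that was run. At an unadjusted p below 0.05 the count on the deposited scale was also 0, the smallest p being 0.590.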

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

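The slope tests on control probe sets and the tests of the intensity-dependent shift as a cause of the list differences were chosen after the result was seen. Groups of 3 were not tested for single deviating arrays, and the series has no second contrast.

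Signals differed in probe sets outside the gene tests. Of 218 probe sets without a gene name, 54 were higher and 6 lower in the mutant in limma. Of 47 vector or reporter probe sets, 1 was higher, from 708 ± 86.5 to 1249 ± 256 (limma adjusted p = 0.00581); what it reads was not resolved. Of 137 Affymetrix control probe sets, 3 were higher and 3 lower. The lower ones read an rRNA, the poly-A control lys and the hybridization control bioD. The 3 higher ones lie along TDH1, a glyceraldehyde-3-phosphate dehydrogenase gene that was itself 1.74-fold higher (803 ± 38.3 to 1397 ± 46.9). A further TDH1 control probe set, with the suffix for shared sequence, did not pass (2250 ± 55.6 to 2070 ± 77.6, log2 -0.12, limma adjusted p = 0.145).

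Dim genes shifted up and bright genes down on the deposited scale. The hybridization and poly-A controls also lay lower, with medians of -0.24 and -0.11, so a fall of bright genes apart from the array scaling was not shown. Compression of the scale at hybridization or scanning would tilt spiked controls as well, and the hybridization controls had a slope of 0.00567 (SE 0.0043), against -0.119 for genes over the same signal range. The poly-A controls, added to the RNA, had a slope of -0.0212 (SE 0.0064), against -0.136 for genes. The 12 dimmest had a median of -0.02 where genes of that signal had 0.32. Several probe sets read the same spiked transcript, so these SEs do not measure the spread between arrays. Against the wild-type mean, single mutant arrays had slopes of -0.051, 0.011 and -0.024 for poly-A controls, and -0.17, -0.11 and -0.13 for genes. These values argue against compression as the whole cause, and with any array left out the gene slope stayed between -0.118 and -0.152, which argues against a single array. A broad effect of H2A R78A on weakly transcribed genes stays open, as does any difference in the RNA itself before the controls were added.

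General stress genes were higher and ribosomal protein genes lower, the pattern of slow or stressed growth. The stress genes kept a median of 0.695 after quantile normalization, which argues against the intensity-dependent shift as their cause, whereas the ribosomal protein genes had a median of -0.02 and may reflect only that shift. Glucose exhaustion at harvest was tested on 10 glucose-repressed genes. Their median was 0.80 on the deposited scale (10 past the threshold in limma) and 0.444 after quantile normalization (7 past the threshold). The standard error of their mean quantile-normalized difference, taken across the genes and not across arrays, was 0.13. HXT7, induced at low glucose, was higher by log2 differences of 0.58 and 0.62 on these scales. HXT1, HXT2, HXT3 and HXT4 did not pass, with differences of 0.23, -0.05, -0.14 and 0.21 on the deposited scale. After quantile normalization these were 0.23, -0.07, -0.06 and -0.11, so the transporter genes did not rise together with HXT7. Less glucose at harvest and a response to the mutation therefore cannot be told apart. The same OD600 range at harvest, 0.5 to 0.7, is recorded for all 6 arrays, which does not give the glucose left in the medium. Growth rates were not used here.

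STE3, a receptor gene of α cells, was 2.22-fold higher (51.6 to 113 ± 8.49; the call ended when low values were raised, limma adjusted p = 0.203), and 4 of 7 a-cell markers were lower: BAR1, MFA1, STE6 and STE2, with log2 differences of -0.42, -0.32, -0.26 and -0.25 (the BAR1 call ended when low values were raised, limma adjusted p = 0.0784). A share of α cells in the mutant cultures could give this, but the quantile-normalized median of MF(ALPHA)1, MF(ALPHA)2 and SAG1 was 0.228, MF(ALPHA)2 not passing (235 ± 5.48 and 233 ± 17.3) and MF(ALPHA)1 dim (19.0 to 66.3), so a small share and weak derepression in a cells cannot be told apart. Loss of silencing at HML would raise its 1 measured gene, HMLALPHA1, which did not rise. The difference of HMLALPHA1 was -0.459 after quantile normalization (SE 0.12) and -0.10 on the deposited scale (SE 0.13). Its signal (102 ± 5.60 and 95.2 ± 12.8) is above the tag controls, which reach 1.94, but below the background level of 232. Its probe set carries the suffix for shared sequence, so this 1 dim gene does not decide whether silencing at HML was lost. The effect of H2A R78A on mating-type genes stays open.

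With 3 arrays against 3 there are 10 splits of the arrays, too few for a share under 0.05. The real split gave 1476 genes and was the only 1 of the 10 with as many. The highest other gave 0, including the 3 others that part every pair of equal numbers. Every other split mixes the genotypes in both groups, so the genotype difference adds to the spread within groups and lowers the calls. Their counts therefore do not measure how many calls would be false.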

How the results depend on the processing

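Cyclic loess and quantile normalization with the replicate block were chosen after seeing the data. Of 2483 comparisons of named genes over 17 settings, 2241 kept their side of the threshold, 236 lost it, 6 gained it and 0 reversed; of 720 comparisons of lists over 19 settings, 622 were the same, 74 weaker, 14 stronger and 10 reversed. A result counts as reversed if the direction changed and it passed in at least 1 of the compared fits; where neither passed, the direction changed in 5 comparisons of genes and 15 of lists, which count as the same. Among the 146 named genes past the threshold, 88 kept call and direction under every alternative set beforehand that tested them. Genes left out by the background filter were not counted as lost under it.

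The 976 higher genes became 566 with quantile normalization, 622 with cyclic loess, 418 with the background filter and 574 with low values raised. The 500 lower genes became 875 with median centring, 312 without trend, 920 with array weights, 857 with the replicate block and 871 with quantile normalization and the block. The total of 1476 became 809 with the filter, 912 with low values raised and 2260 with array weights. Stricter thresholds gave 722 genes (584 higher, 138 lower) at an adjusted p below 0.01, 456 (439 and 17) at 1.5-fold and 142 (141 and 1) at 2-fold. With each array left out the total ranged from 888 (without mutant replicate 3) to 1686 and the lower genes from 194 to 601; without mutant replicate 1 there were 911 in all and 228 lower, and without wild-type replicates 1 and 2 there were 228 and 308 lower. The filter kept 78 of the named genes, fewer being tested, and raising low values kept 97.

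Of 38 lists 23 passed in limma's camera, 15 with the filter (36 lists tested) and 0 with an estimated correlation, where 5 had an unadjusted p below 0.05. That setting changes the p-values and not the medians, which are 0.744 (general stress), 0.559 (meiosis), 0.488 (thiamine), 0.472 (mannoproteins), -0.121 (ribosome biogenesis) and -0.167 (ribosomal proteins). The ribosomal protein median was -0.02 with quantile normalization, with or without block, and -0.012 with cyclic loess. Directions reversed for heat shock factor targets (0.031 with quantile normalization, with or without block, 0.04 with cyclic loess), glycolysis (0.026 with quantile normalization, with or without block), the proteasome (median -0.009 with quantile normalization, with or without block, -0.01 with cyclic loess) and, with fry, inositol (median -0.065) and pheromone genes (-0.019).

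The telomere-proximal excess of the median, 0.107, was -0.012 with quantile normalization (with or without block), 0.001 with cyclic loess, where the test reversed, 0.019 with the filter, 0 with low values raised, 0.122 for the first 4 genes, 0.048 for the first 16 and 0.107 with an estimated correlation (p no longer past the threshold); with arrays left out it ranged from 0.079 to 0.158. The share lower was 20.3% with quantile normalization, 27.3% with the block added, 16.3% with cyclic loess, 18.6% with the filter, 10.5% with low values raised and 10.5% without trend, and 6.98% to 12.2% with arrays left out. The share higher was 22.1% for the first 4 genes and no longer passed. The cause was not tested, apart from fewer genes under the filter and fewer arrays when left out. The block changed no other call of these results. Robust camera was not run, as camera has no such option. Signal over background limits dim genes: 2 tested genes lay at or under the highest tag control on every array, and the 246 genes with a mean log2 signal below 6 had a median difference of 0.51 on the deposited scale and -0.06 after quantile normalization.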

Other observations

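Of 29 genes under nitrogen catabolite repression, 14 were higher and 2 lower (15 and 2 adjusted over the list alone; median log2 0.30, limma camera adjusted p = 0.00262, 0.248 with an estimated correlation), led by the regulator gene DAL80 (32.0 ± 5.04 to 101.3 ± 5.11) and the allantoinase gene DAL1 (69.4 ± 2.11 to 168 ± 4.44). After quantile normalization 11 were higher and 1 lower, with a median of 0.07. The list then passed in limma's camera (adjusted p = 0.014), but not with an estimated correlation (0.204). On the deposited scale it did not pass in camera with the background filter (adjusted p = 0.195). The DAL80 call ended when low values were raised. Glucose transport genes were higher in 8 of 18 cases (10 adjusted over the list alone). Their limma camera adjusted p was 0.00304, or 0.248 with an estimated correlation. Their median log2 difference was 0.42, and 0.09 after quantile normalization with 6 higher. There the limma camera adjusted p was 0.0164, or 0.24 with an estimated correlation. HXT9, which has a near-identical copy, rose 2.37-fold and HXT5 2.02-fold; with low values raised the list did not pass (limma camera adjusted p = 0.0886). Genes of drug response and detoxification were higher in 11 of 31 cases and lower in 1 (11 and 2 adjusted over the list alone; limma camera adjusted p = 0.0327, 0.0711 without mutant replicate 2, 0.0544 with array weights, 0.0595 on ranks, 0.0766 with low values raised, 0.247 with the background filter, 0.248 with an estimated correlation). The galactose regulon had 4 of 9 members higher and 1 lower (the same adjusted over the list alone). Its median log2 difference was 0.295, and genes of matched signal had a median of 0.281. Its limma camera adjusted p was 0.0409, or 0.265 with an estimated correlation. The list did not pass in camera after quantile normalization (0.391) or with low values raised (0.517). It also did not pass without wild-type replicate 1 (0.059), wild-type replicate 3 (0.0632) or mutant replicate 1 (0.0693).

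Among amino acid genes under Gcn4, 18 of 50 were lower and 6 higher (18 and 6 adjusted over the list alone; median log2 -0.15, limma camera adjusted p = 8.79e-04, 0.115 after quantile normalization, 0.248 with an estimated correlation). HIS7 was 1.34-fold lower, while SER3, for serine synthesis, was 2.29-fold higher (236 ± 14.2 to 541 ± 20.7). The iron regulon, with FIT2 and ENB1, had 6 of 30 members lower and 4 higher (the same adjusted over the list alone; limma camera adjusted p = 0.023, 0.0601 without wild-type replicate 1, 0.110 with low values raised, 0.410 with an estimated correlation), and 10 lower and 0 higher after quantile normalization. In ergosterol synthesis 5 of 27 were lower (5 adjusted over the list alone; limma camera adjusted p = 0.0312, 0.671 after quantile normalization, 0.0668 with array weights, 0.098 with low values raised, 0.195 with the background filter, 0.0704 without wild-type replicate 3, 0.0817 without mutant replicate 1, 0.265 with an estimated correlation), with ERG12 1.43-fold lower. The a-cell markers (4 of 7 lower, 4 adjusted over the list alone) had a limma camera adjusted p of 0.00931, 0.0828 after quantile normalization and 0.265 with an estimated correlation. Proteasome genes were lower in 3 of 35 cases (0 adjusted over the list alone; limma camera adjusted p = 0.00636, 0.699 after quantile normalization, 0.0889 with the background filter, 0.081 without mutant replicate 1, 0.525 with an estimated correlation), and histone chaperones and silencing factors in 1 of 22, SIR2, or in 4 after quantile normalization (1 adjusted over the list alone; limma camera adjusted p = 0.0471, 0.248 with an estimated correlation), a call that ended with low values raised (0.120), with the background filter (0.210) and without any array other than wild-type replicate 3 (0.0531 to 0.0662).

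The other lists did not pass in limma's camera, with adjusted p of 0.0528 for branched-chain amino acids (1 higher and 3 lower of 15), 0.0583 for α-cell markers (3 and 0 of 5), 0.149 for seripauperins (5 and 1 of 13), 0.184 for zinc (5 and 0 of 14), 0.267 for mitochondrial ribosomal proteins (5 and 4 of 69) and 0.385 for genes with reported cryptic promoters (2 and 0 of 11). For methionine it was 0.414 (8 and 2 of 30), for pyrimidines 0.421 (1 and 3 of 10), for histone genes 0.421 (0 and 1 of 10), for pheromone response genes 0.631 (8 and 8 of 34) and for glycolysis 0.680 (6 and 5 of 24). For cell wall integrity it was 0.699 (9 and 3 of 30), for heat shock factor targets 0.699 (5 and 2 of 28), for inositol 0.752 (3 and 2 of 18) and for M/G1 genes 0.787 (5 and 2 of 26). After quantile normalization glycolysis (0.0351), cell wall integrity (0.035) and heat shock factor targets (0.00921) passed as higher in limma's camera, and with an estimated correlation they did not (adjusted p of 0.240, 0.426 and 0.574). The α-cell markers passed with median centring (0.040) and without wild-type replicate 2 (0.0433) or mutant replicate 3 (0.0423), branched-chain genes without mutant replicate 3 (0.0332) and zinc genes without wild-type replicate 3 (0.044). Individual members rose, among them the chaperone gene SSA4 (460 ± 20.6 to 959 ± 60.4) and OPI3 of phospholipid synthesis (580 ± 26.2 to 1016 ± 5.93).

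Hypotheses on chromatin were tested too. If nucleosome changes spread to neighbours, adjacent genes would change together. Across 2867 adjacent pairs of genes above the background level, the correlation of the quantile-normalized differences was 0.0344. It lay within the range of -0.0331 to 0.0404 from reshuffled genes (permutation p = 0.066, adjusted p = 0.13), which argues against a strong effect among these genes. For 750 divergent pairs it was 0.0802, outside the reshuffled range of -0.0649 to 0.0781 (permutation p = 0.029), and did not pass after adjustment (adjusted permutation p = 0.12). Pairs with a dimmer gene were left out, so the test does not cover weakly expressed genes. Longer genes could depend more on nucleosomes during elongation. Across 4086 genes above background the Spearman correlation of gene length with the difference was -0.11 after quantile normalization and -0.02 on the deposited scale, so an effect of length and an effect of the scaling cannot be told apart.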
